A study of Mus musculus with 18 samples.

How the data were processed

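RNA sequencing of the apex of mouse hearts was analysed in 18 libraries, 3 in each of 6 groups, with no sample column left out. Per the labels' protocols, tissue was kept in RNAlater, RNA was extracted with Trizol, and polyadenylated RNA was made into directional libraries. Per the submitters' processing notes, the mouse genome build was mm10 and the tools were HISAT2 2.0.5, featureCounts 1.5.0-p3, StringTie 1.3.3b and DESeq2 1.20.0, with no role stated for any of them. The count values are deposited by the authors as integers per gene with no scaling. The FPKM values are deposited too, and were made by the authors as the count per kilobase of gene length relative to an adjusted library size, as the values themselves show. Whether counting used the strand is not given in the sources used here, so genes that overlap a neighbour on the other strand are uncertain. What the control hearts received is not given in the sources used here beyond the word control.

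The counts held 54532 genes, of which 17876 passed filterByExpr, and 102 symbols stood under more than 1 gene ID. Libraries held between 31418657 and 41259968 counts, so that 3 counts equal between 0.0622 and 0.108 CPM, the count relative to the scaled library total. No 2 libraries of a group were duplicates by their counts. The chi-square per degree of freedom between replicates ranged from 6.38 to 43.4, against 1 for counting noise alone. Xist had between 0 and 12 counts in every library, while the Y-linked genes Ddx3y (2772 to 3811), Kdm5d (597 to 871), Uty (683 to 915) and Eif2s3y (1963 to 2741) were present in all.

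Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and all 18 libraries in a single fit of 6 groups, which left 12 residual degrees of freedom. The common dispersion was 0.00834, a biological coefficient of variation of 9.13%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Contrasts compared shRNA with control, lamin with shRNA and lamin with control within each batch, shRNA with control over both batches, and the differences of these effects between the batches. Standard errors were taken from the F statistic of each contrast. Gene lists were tested with camera of limma 3.58.1, with its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within each contrast. A score of shRNA-responsive genes took the mean log2 CPM (prior count 2) over genes called in the other batch, signed by direction there, and groups were compared by an exact permutation test of 3 against 3 libraries. Counts were simulated with the mean of each gene of these data and, in place of its own dispersion, that of the fitted trend. Known changes of 1.5-, 2- and 4-fold were added to 67, 67 and 66 genes above 1 CPM in the shRNA group of batch LC. With 17342 genes tested, edgeR recovered 71.64% of 1.5-fold, 92.54% of 2-fold and 100% of 4-fold changes between shRNA and control with 12 false calls. For the difference between the batches edgeR recovered 50.75%, 80.6% and 100% with 9 false calls. Far fewer genes changed than were called in the real hearts, so recovery there may differ.

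The 32 lists, fixed before the data were seen, covered nuclear lamina partners, fetal and stress genes of cardiomyocytes, sarcomere, ion channels, calcium handling, extracellular matrix, fatty acid oxidation, the respiratory chain, mitochondrially encoded genes, glycolysis, the integrated stress response, the unfolded protein response, heat shock proteins, autophagy, p53 targets, MAPK targets, interferon response, cell cycle and the core clock. A further 13 lists among them were markers of cell types. The lists held 492 different genes, 4 of them on more than 1 list. At 1 CPM or more in the controls stood 16 of 16 macrophage, 10 of 10 fibroblast and 12 of 12 endothelial markers, but only 1 of 14 T and natural killer cell, 2 of 10 B cell, 1 of 9 neutrophil, 2 of 9 skeletal muscle, 0 of 8 adipocyte and 1 of 6 mesothelial markers.

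Named genes followed a rule written before the data were seen: Lmna; the 6 largest rises and 6 largest falls among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between the replicates of the groups; and up to 4 called members of each list by smallest p. For differences between effects the condition on overlap was dropped, and a gene named in any comparison may be given in the others. Some genes the rule names are not reported here. Where a group held at most 3 counts of a gene over its libraries, the ratio of counts is given with a 95% counting interval in place of a fitted fold change.

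Alternatives planned before the data were seen were DESeq2 1.42.0, RLE size factors, no filter on low counts, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with an FPKM of at least 1 in 3 or more libraries, removal of mitochondrially encoded genes, a fit of the compared groups alone, the replicate number as a block, the late-numbered control of each batch left out, each library left out in turn, and scores restricted to genes of at least 1.5-fold change or without Lmna. The late-numbered controls were the third of each batch, numbered 827 (batch LC) and 826 (batch LA) in the labels. Scaling by library totals without TMM factors was added after the data were seen. Lamin isoforms could not be separated in counts per gene.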

Results

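Gene expression was measured by RNA sequencing of polyadenylated RNA from the apex of mouse hearts. The series addressed what raising lamin A or lamin C, carried by an adeno-associated virus of serotype 9 (rAAV9), does in a mouse model of dilated cardiomyopathy made by knocking down Lmna. The 18 libraries fell into 6 groups of 3 libraries in 2 batches. Batch LC held control hearts, hearts labelled Lmna shRNA, and hearts labelled Lmna shRNA with lamin C. Batch LA held control hearts, hearts labelled Lmna shRNA, and hearts labelled Lmna shRNA with lamin A. All were labelled wild type in genotype, and each lamin was present in 1 batch, so the lamin and the batch cannot be told apart except through each batch's own control and shRNA hearts. Gene counts summed to between 31418657 and 41259968 per library, and 17876 of 54532 genes passed the filter on low counts. Mitochondrially encoded genes took 25.4% ± 0.147 (SD, n = 3) of the counts in the controls of batch LC, 14.4% ± 1.36 in the hearts labelled Lmna shRNA and 24% ± 0.799 with lamin C. In batch LA they took 26.7% ± 0.326 in the controls, 14.4% ± 0.56 in the hearts labelled Lmna shRNA and 21.3% ± 1.15 with lamin A. Changes are given as log2 fold changes ± standard error from edgeR, with 3 libraries in each group. The p-values measure spread between these samples, and the labels say nothing of cages or litters.

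The target of the shRNA was examined first. Lmna, which encodes lamins A and C by alternative splicing (ENSMUSG00000028063, chromosome 3, 88480147 to 88509956, minus strand, mm10), was not lower in the hearts labelled Lmna shRNA. The 3 controls of batch LC held 122, 128 and 120 CPM (counts relative to the scaled library total), and the 3 hearts labelled Lmna shRNA held 137, 134 and 115. In batch LA the controls held 120.0, 119.6 and 112 CPM and the hearts labelled Lmna shRNA held 127, 122 and 130.3. The change was 0.06 ± 0.08 in batch LC (edgeR adjusted p = 0.578) and 0.11 ± 0.08 in batch LA (edgeR adjusted p = 0.258), and with libraries scaled by their totals alone it was 0.48 and 0.55 and was called higher (edgeR adjusted p = 7.24e-05 and 1.65e-05). Lmna rose with each added lamin. Hearts with lamin C held 1317, 1064 and 1375 CPM, an increase of 3.29 ± 0.09 over hearts labelled Lmna shRNA, and hearts with lamin A held 556, 537 and 501, an increase of 2.07 ± 0.08. Gene counts separate neither the lamin A from the lamin C transcript nor a transcript of the virus from that of the mouse gene. Because the counts of Lmna did not fall, the groups are called by their labels throughout, and every direction given for the shRNA rests on those labels.

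**Figure D1:**
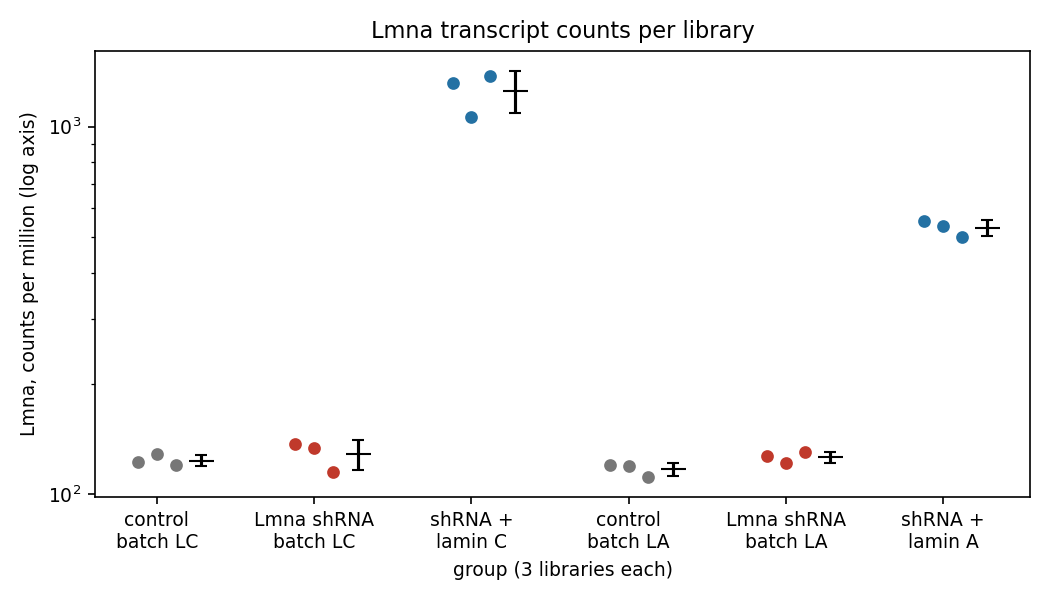
Lmna in CPM (log axis) in each of the 18 libraries, by group; points are libraries, and the black bar beside them is the mean with its SD. Hearts labelled Lmna shRNA averaged 128.4 (batch LC) and 126.3 (batch LA) against 123.5 and 117.1 in the controls, while hearts with lamin C averaged 1252 and hearts with lamin A 531.3.

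The first comparison asked how hearts labelled Lmna shRNA differed from the controls of batch LC, in which Lmna itself was not lower. Genes of scar formation and of the fetal and stressed heart rose, while genes of contraction, electrical conduction and oxidative metabolism fell. All 30 measured genes of extracellular matrix and fibrosis rose, among them Timp1, an inhibitor of matrix proteases (5.86 ± 0.25), Postn, the periostin of activated fibroblasts (5.49 ± 0.24), Col8a1, a short-chain collagen (4.07 ± 0.18), and Bgn, the proteoglycan biglycan (3.09 ± 0.13). Their list had a median change of 3.27 (camera adjusted p = 1.2e-32, and adjusted p = 0.037 with an estimated correlation). Markers of fibroblasts moved with them: 8 of 10 rose, led by Mfap5 (3.58 ± 0.15), Pi16 (2.13 ± 0.13) and Dcn (1.46 ± 0.08). Their median was 1.11 (camera adjusted p = 5.6e-05, and adjusted p = 0.13 with an estimated correlation). Of 14 fetal and stress genes of cardiomyocytes, 13 rose, including Nppa, the precursor of atrial natriuretic peptide (6.12 ± 0.42), Nmrk2, a nicotinamide riboside kinase (5.51 ± 0.32), Tubb3, a beta tubulin (3.65 ± 0.23), and Uchl1, a deubiquitinating enzyme (3.63 ± 0.21). The median of that list was 2.69 (camera adjusted p = 1.2e-06, and adjusted p = 0.13 with an estimated correlation). Among protein-coding genes at 5 CPM or more, large rises were those of Sprr1a, a stress-induced proline-rich protein (9.43 ± 0.54), Cthrc1, a secreted protein of collagen-producing fibroblasts (9.14 ± 0.67), and 1500015O10Rik (7.67 ± 0.61). Comp (7.66 ± 0.53) and Thbs4 (7.46 ± 0.38), both matrix glycoproteins of the thrombospondin family, followed; Cthrc1, Comp and Thbs4 are on the matrix list. Chil1, a chitinase-like protein, had 1654 counts in the hearts labelled Lmna shRNA and 1 in the controls, a ratio of 1150 with a 95% counting interval of 206 to 45500.

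In the same comparison, Clcn1, a chloride channel (-6.13 ± 0.36), Ces1d, a carboxylesterase (-4.87 ± 0.33), Mylk4, a kinase of the myosin light chain kinase family (-4.66 ± 0.25), Kcnv2, a modifier of potassium channels (-4.48 ± 0.25), Scn4b, a beta subunit of sodium channels (-4.44 ± 0.35), and Cyp26b1, which degrades retinoic acid (-4.43 ± 0.8), had large falls (edgeR adjusted p of 7.92e-05 or less). Of 22 ion channel and gap junction genes, 21 fell and 1 rose, at a median of -1.05 (camera adjusted p = 6.1e-14, and adjusted p = 0.024 with an estimated correlation). Kcnip2 fell by 2.74 ± 0.15, Abcc9 by 1.74 ± 0.09 and Kcnj11 by 1.37 ± 0.06. Among 15 calcium handling genes 11 fell and 2 rose (camera adjusted p = 2.8e-05, and adjusted p = 0.024 with an estimated correlation). Hrc fell by 2.68 ± 0.15, the calcium pump Atp2a2 by 1.89 ± 0.1 and its inhibitor Pln by 1.71 ± 0.07. Sarcomere genes fell in 17 of 18 cases (camera adjusted p = 1.4e-08, and adjusted p = 0.024 with an estimated correlation). With libraries scaled by their totals 12 sarcomere genes were called lower and 1 higher, and 9 calcium handling genes lower and 5 higher. Cardiac troponin I (Tnni3) fell by 1.82 ± 0.08 and Myl2 by 1.32 ± 0.06. Fatty acid oxidation genes fell in 24 of 25 cases, with a median of -1.71, including the dehydrogenases Acadm (-1.76 ± 0.06) and Acadvl (-1.71 ± 0.08) and the trifunctional enzyme subunit Hadha (-1.7 ± 0.07) (camera adjusted p = 5.1e-28, and adjusted p = 0.024 with an estimated correlation). All 35 nuclear-encoded genes of the respiratory chain fell, by a median of 1.13 (camera adjusted p = 1.1e-28, and adjusted p = 0.066 with an estimated correlation). Sdha fell by 1.49 ± 0.06 and Ndufa10 by 1.3 ± 0.06. Of 13 mitochondrially encoded genes 12 fell, mt-Co1 by 1.19 and mt-Nd5 by 1.36 (camera adjusted p = 1.2e-06, and adjusted p = 0.097 with an estimated correlation); nuclear copies of such genes make their single values uncertain. Glycolysis genes divided into 10 lower and 6 higher, and their median of -0.19 turned to 0.24 when libraries were scaled by their totals (camera adjusted p = 0.021, and adjusted p = 0.3 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter, fell by 1.91 ± 0.1 and Eno3 by 1.67 ± 0.08.

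Stress and immune genes rose as well. Interferon response genes rose in 28 of 29 cases (camera adjusted p = 4.3e-21, and adjusted p = 0.055 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose by 3.9 ± 0.18, Ifit1 by 2.88 ± 0.15 and Irf7 by 2.63 ± 0.12. Beside them, 14 of 16 macrophage and monocyte markers rose and 1 fell, at a median of 1.82 (camera adjusted p = 7.8e-18, and adjusted p = 0.024 with an estimated correlation). Lgals3 rose by 6.54 ± 0.19 and the complement genes C1qb by 2.03 ± 0.07 and C1qa by 1.96 ± 0.06. Of 14 markers of T and natural killer cells 12 rose, among them Ccl5 (4.35 ± 0.38) and Cd3g (2.73 ± 0.49), although these genes were at low counts (camera adjusted p = 0.019, and adjusted p = 0.22 with an estimated correlation). Targets of the integrated stress response rose in 18 of 22 cases and fell in 2 (camera adjusted p = 1.7e-05, and adjusted p = 0.037 with an estimated correlation). Gdf15, a secreted stress cytokine, rose by 4.72 ± 0.26, Nupr1 by 3.11 ± 0.17 and the serine synthesis enzyme Psat1 by 2.44 ± 0.13, while Vldlr, a lipoprotein receptor on the list, fell by 1.27. Targets of p53 rose in 15 of 19 cases and fell in 2 (camera adjusted p = 8.7e-05, and adjusted p = 0.037 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 3.32 ± 0.23 and Phlda3 by 2.73 ± 0.09. All 15 cell cycle genes rose, among them Birc5 (2.16 ± 0.27) and Top2a (1.44 ± 0.26) (camera adjusted p = 0.019, and adjusted p = 0.64 with an estimated correlation). The third library labelled Lmna shRNA lay nearer to the controls in these genes, with Bub1 at 0.56 CPM against 2.61 and 2.35 in the other shRNA libraries and 0.62, 0.53 and 0.93 in the controls. The list did not pass camera without the second library labelled Lmna shRNA (adjusted p = 0.0513) or with the compared groups alone (adjusted p = 0.0613). MAPK targets and immediate early genes rose in 11 of 18 cases and fell in 1 (camera adjusted p = 0.0095, and adjusted p = 0.44 with an estimated correlation). Egr2 rose by 3.99 ± 0.3, Etv4 by 2.88 ± 0.26 and Myc by 1.92 ± 0.22. Among heat shock proteins and chaperones 7 of 13 rose and 3 fell (camera adjusted p = 0.048, and adjusted p = 0.44 with an estimated correlation). This list did not pass without the first or the second control (adjusted p = 0.0517 and 0.0637). Hspb1 rose by 1.7 ± 0.11 and Hsp90aa1 by 1.28 ± 0.11; Hspa1b (4.22 ± 0.23) and Hspa1a (3.06 ± 0.23) are near-identical copies whose counts could be shared.

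The other lists did not pass the camera test in this comparison, except the endothelial and skeletal muscle markers. Of 12 endothelial markers 11 fell and 1 rose, at a median of -0.56 that was -0.13 with 4 lower calls under library totals (camera adjusted p = 0.0032, and adjusted p = 0.22 with an estimated correlation). Kdr, a receptor for vascular endothelial growth factor, fell by 1.26 ± 0.12 and Cdh5 by 0.79 ± 0.06. Skeletal muscle markers rose in 6 of 8 cases (camera adjusted p = 0.019, and adjusted p = 0.066 with an estimated correlation). Tnnt3 rose by 2.58 ± 0.31 and Myl1 by 2.07 ± 0.12. Genes of the unfolded protein response of the endoplasmic reticulum rose in 8 of 13 cases and fell in 1 (camera adjusted p = 0.22). Edem1 stood at 1.12 ± 0.07 and Herpud1 at -1.1 ± 0.15. Partners of the nuclear lamina held 4 higher and 7 lower genes of 19, and their median of -0.05 turned to 0.38 with 14 higher and 0 lower calls under library totals (camera adjusted p = 0.7). Tmem43, an inner nuclear membrane protein linked to inherited cardiomyopathy, stood at 1.31 ± 0.07 and Lbr at -0.5 ± 0.06, or -0.07 and not called under library totals (edgeR adjusted p = 0.291). Autophagy and atrophy genes divided into 7 higher and 6 lower of 15 (camera adjusted p = 0.7). Ctsl stood at 0.95 ± 0.07 and Trim63 at -0.95 ± 0.07. Core clock genes held 2 higher and 6 lower of 15 (camera adjusted p = 0.61), against controls among which the third control library stood apart on them (Arntl 0.75, 1.37 and 26.2 CPM). Of the other lists, atrial markers, which share 4 genes with other lists, held 4 higher and 1 lower of 8 (camera adjusted p = 0.17). Smooth muscle and pericyte markers held 4 higher and 5 lower of 10, at a median of -0.24 against a mean of 0.36 and a median of 0.18 under library totals (camera adjusted p = 0.7). Cnn1 stood at 4.44 ± 0.31 and Rgs5 at -0.86 ± 0.06. B cell markers held 3 higher and 1 lower of 10 (camera adjusted p = 0.7), neutrophil markers 2 higher of 4 (0.24), adipocyte markers 1 higher of 5 (0.74) and Schwann cell markers 2 higher and 1 lower of 6 (0.61). The 5 erythroid markers fell, with a median of -1.32, though 0 were called under library totals and the globin copies Hba-a1 and Hba-a2 can share reads (camera adjusted p = 0.42). Without the first library labelled Lmna shRNA, Hba-a1 (-0.81, edgeR adjusted p = 0.162) and Hba-a2 (-1.29, edgeR adjusted p = 0.0776) were not called, and by DESeq2 Hba-a1 was not (-1.14, adjusted p = 0.0763). None of 5 mesothelial markers was called, and their median of -0.23 turned to 0.2 under library totals (camera adjusted p = 0.88).

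In total 11247 genes (62.9%) changed between hearts labelled Lmna shRNA and the controls of batch LC, 5948 higher and 5299 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05), and 2894 and 1479 of them by at least 2-fold. The share called higher was 52.9% with trimmed-mean (TMM) scaling and 81.2% of 12844 genes with library totals, a scaling that moved the median of all genes up by 0.43. Counts of list members adjusted over the list alone equalled those over all genes tested, except for 2 higher and 7 lower lamina partners, 12 and 1 MAPK targets, 2 and 1 B cell markers, and 4 and 6 smooth muscle markers.

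Batch LA gave a second comparison of hearts labelled Lmna shRNA with controls, again with no fall in Lmna. Sprr1a (8.78 ± 0.49), Cthrc1 (8.19 ± 0.59), Thbs4 (7.39 ± 0.38), Fmod, a collagen-binding proteoglycan (7.35 ± 0.53), and Comp (7.03 ± 0.52) had large rises, and Chil1 had 731 counts against 3 in the controls, a ratio of 172 (95% counting interval 58.5 to 834). Clcn1 (-4.91 ± 0.33), Ces1d (-4.59 ± 0.32), Kcnv2 (-4.45 ± 0.24), Scn4b (-4.04 ± 0.35), Mylk4 (-3.85 ± 0.25) and Smco1 (-3.45 ± 0.24) had large falls. All 30 matrix genes rose (camera adjusted p = 2.5e-32, and adjusted p = 0.037 with an estimated correlation). Timp1 rose by 5.68 ± 0.24 and Postn by 5.37 ± 0.24. Fibroblast markers rose in 8 of 10 cases and fell in 1 (camera adjusted p = 0.00017, and adjusted p = 0.17 with an estimated correlation). 13 of 14 fetal and stress genes rose (camera adjusted p = 4.1e-07, and adjusted p = 0.11 with an estimated correlation). Nmrk2 rose by 5.32 ± 0.31 and Nppa by 5.28 ± 0.4. Genes of fatty acid oxidation fell in 25 of 25 cases, with Acadm at -1.75 ± 0.06 (camera adjusted p = 1.2e-29, and adjusted p = 0.023 with an estimated correlation). All 35 respiratory chain genes fell, with Ndufv1 at -1.24 ± 0.05 (camera adjusted p = 3.7e-28, and adjusted p = 0.07 with an estimated correlation). Sarcomere genes fell in 17 of 18 cases, with Myl2 at -1.42 ± 0.06 (camera adjusted p = 2.3e-08, and adjusted p = 0.023 with an estimated correlation). Ion channel genes fell in 21 of 22 cases and rose in 1, with Kcnj3 at -2.73 ± 0.15 (camera adjusted p = 8.2e-15, and adjusted p = 0.023 with an estimated correlation). Macrophage markers rose in 14 of 16 cases and fell in 1 (camera adjusted p = 1.7e-18, and adjusted p = 0.023 with an estimated correlation). Lgals3 rose by 6.18 ± 0.19 and C1qa by 1.88 ± 0.06. Interferon genes rose in 29 of 29 cases (camera adjusted p = 1.2e-20, and adjusted p = 0.07 with an estimated correlation). Zbp1 rose by 3.83 ± 0.18 and Ifi27l2a by 3.09 ± 0.17. Stress response targets rose in 16 of 22 cases and fell in 2 (3 lower adjusted over the list alone) (camera adjusted p = 0.00014, and adjusted p = 0.055 with an estimated correlation). Gdf15 rose by 4.21 ± 0.24 and Psat1 by 2.51 ± 0.13. Endothelial markers fell in 11 of 12 cases and rose in 1 (camera adjusted p = 0.0038, and adjusted p = 0.24 with an estimated correlation). Cdh5 fell by 0.73 ± 0.06 and Kdr by 0.95 ± 0.12. Calcium handling genes fell in 11 of 15 cases and rose in 2 (camera adjusted p = 1.6e-05, and adjusted p = 0.023 with an estimated correlation). Under library totals 10 sarcomere genes were called lower and 3 higher, and 8 calcium handling genes lower and 4 higher. Endothelial markers then held 4 lower and 2 higher calls, at a median of -0.12. Targets of p53 rose in 14 of 19 cases and fell in 2 (camera adjusted p = 9.9e-05, and adjusted p = 0.036 with an estimated correlation). Markers of T and natural killer cells rose in 11 of 14 cases (camera adjusted p = 0.029, and adjusted p = 0.24 with an estimated correlation) and skeletal muscle markers in 6 of 8 (camera adjusted p = 0.019, and adjusted p = 0.07 with an estimated correlation). By camera with its preset correlation the mitochondrially encoded list was also lower, and the heat shock, MAPK and cell cycle lists were higher. With an estimated correlation none of these passed (camera adjusted p = 0.071, 0.24, 0.44 and 0.49). For the lists of this paragraph other than the stress response targets, the counts adjusted over the list alone equalled those over all genes. In all, 10975 genes changed by the edgeR test, 5784 higher and 5191 lower. With library totals, which moved the median by 0.44, 82.4% of 12907 called genes were higher, against 52.7%.

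Hearts labelled Lmna shRNA changed alike in the 2 batches in most genes that were called. Of the 5948 genes higher in batch LC, 5099 were also higher in batch LA, where 1925 would be shared by independent lists, and 4588 of the 5299 lower genes were also lower in batch LA, against 1539. Opposite calls were made for 1 gene higher in batch LC and 5 genes lower in batch LC. The fold changes of the batches, which share no library, correlated across 17876 genes with a Pearson r of 0.91 and a Spearman rho of 0.906, where genes are not independent replicates. A test of the difference between the batches called 1 gene by edgeR, with 1143 genes at an unadjusted p under 0.05 and 9 called by DESeq2. No listed gene differed between the batches, and adjusted over the list alone 1 lamina partner, 1 glycolysis gene and 1 clock gene did. The matrix, stress response and heat shock lists had medians of 0.18, 0.17 and -0.16 (camera adjusted p = 0.016 for each, and adjusted p = 0.92 with an estimated correlation). None of the 3 passed without the first control of batch LA (adjusted p = 0.169, 0.169 and 0.164) or the first library labelled Lmna shRNA of batch LA (adjusted p = 0.103, 0.103 and 0.197). Without the third control library of batch LC 47 genes differed, without the filter on low counts 247, and without the second control library or the second shRNA library of batch LA 0. Over both batches together 12899 genes changed by the edgeR test, 6861 higher and 6038 lower, and with library totals, which moved the median by 0.43, 81.1% were higher, against 53.2%.

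Lamin C was examined by comparing hearts with shRNA and lamin C with hearts labelled Lmna shRNA alone. Genes low in the hearts labelled Lmna shRNA were higher with lamin C. Scn4b (5.09 ± 0.35), Clcn1 (4.89 ± 0.38), Ces1d (4.51 ± 0.32), Mylk4 (3.9 ± 0.25) and Kcnv2 (3.6 ± 0.25) had large rises. The short mitochondrial gene mt-Atp8, of which nuclear copies exist, stood at 3.45 ± 0.93, but at 0.99 and not called without the third lamin C library (edgeR adjusted p = 0.252). Chil1 (-5.37 ± 0.56), the serine protease inhibitors Serpinb9b (-4.49 ± 0.28) and Serpinb1a (-4.35 ± 0.17), Comp (-4.35 ± 0.41) and Slfn4, a Schlafen gene of myeloid cells (-4.24 ± 0.31) had large falls. All 30 matrix genes fell (camera adjusted p = 5.2e-25, and adjusted p = 0.052 with an estimated correlation). Lox, which crosslinks collagen, fell by 3.59 ± 0.22, Timp1 by 2.78 ± 0.19 and Bgn by 2.02 ± 0.12. Fibroblast markers fell in 8 of 10 cases, with Mfap5 at -2.17 ± 0.14 (camera adjusted p = 0.00035, and adjusted p = 0.19 with an estimated correlation). Macrophage markers fell in 14 of 16 cases with 1 higher, with Lgals3 at -3.18 ± 0.15 (camera adjusted p = 1.3e-10, and adjusted p = 0.048 with an estimated correlation). Fetal and stress genes fell in 12 of 14 cases (camera adjusted p = 4e-05, and adjusted p = 0.19 with an estimated correlation). Nppa fell by 3.06 ± 0.36 and Uchl1 by 2.99 ± 0.19. Interferon genes fell in 28 of 29 cases (camera adjusted p = 8e-18, and adjusted p = 0.071 with an estimated correlation). Zbp1 fell by 2.36 ± 0.16 and Irf7 by 1.85 ± 0.11. Fatty acid oxidation genes rose in 24 of 25 cases (camera adjusted p = 6.3e-30, and adjusted p = 0.04 with an estimated correlation). Acadm rose by 1.49 ± 0.06 and Hadha by 1.4 ± 0.07. All 35 respiratory chain genes rose, with Sdha at 1.16 ± 0.06 (camera adjusted p = 5.7e-30, and adjusted p = 0.071 with an estimated correlation). Ion channel genes rose in 20 of 22 cases and fell in 1 (camera adjusted p = 2.3e-14, and adjusted p = 0.04 with an estimated correlation). Kcnj3 rose by 2.14 ± 0.14 and Kcnip2 by 2.12 ± 0.14. Sarcomere genes rose in 16 of 18, with Tnni3 at 1.54 ± 0.08 (camera adjusted p = 2e-08, and adjusted p = 0.04 with an estimated correlation). Stress response targets fell in 17 of 22 cases (18 adjusted over the list alone) and rose in 2 (camera adjusted p = 0.00045, and adjusted p = 0.071 with an estimated correlation). Nupr1 fell by 2.35 ± 0.16 and Psat1 by 1.6 ± 0.12. Unfolded protein response genes fell in 9 of 13 cases and rose in 1 (camera adjusted p = 0.033, and adjusted p = 0.57 with an estimated correlation). This list did not pass without the first library labelled Lmna shRNA (adjusted p = 0.0629) or the third lamin C library (adjusted p = 0.0552). Calcium handling genes rose in 10 of 15 cases and fell in 3 (10 and 4 adjusted over the list alone) (camera adjusted p = 0.00027, and adjusted p = 0.048 with an estimated correlation). Targets of p53 fell in 13 of 19 cases and rose in 2 (camera adjusted p = 0.00023, and adjusted p = 0.048 with an estimated correlation). Skeletal muscle markers fell in 6 of 8 cases (7 adjusted over the list alone) (camera adjusted p = 0.0027, and adjusted p = 0.045 with an estimated correlation), and endothelial markers rose in 9 of 12 and fell in 1 (camera adjusted p = 0.013, and adjusted p = 0.33 with an estimated correlation). Under library totals 4 endothelial markers were called higher and 2 lower. Sarcomere genes then held 11 higher and 1 lower calls, and calcium handling genes 8 and 5. By camera with its preset correlation the mitochondrially encoded and glycolysis lists were also higher, the latter not without the first library labelled Lmna shRNA (adjusted p = 0.0629). Neither passed with an estimated correlation (camera adjusted p = 0.071 and 0.36). The other list counts of this paragraph were equal when adjusted over the list alone. The edgeR test called 9662 genes, 4592 higher and 5070 lower. With library totals, which moved the median by -0.31, 20.2% of 11550 called genes were higher, against 47.5%.

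Against the controls of batch LC, hearts with shRNA and lamin C differed in 2690 genes by the edgeR test, 1585 higher and 1105 lower, of which 554 and 31 differed by at least 2-fold. Among protein-coding genes at 5 CPM or more, Thbs4 (4.21 ± 0.35), Gdf15 (4.03 ± 0.28), Gm4841 (3.42 ± 0.64), Serpina3n, an acute phase protease inhibitor (3.4 ± 0.32), and Lgals3 (3.36 ± 0.19) were far above the control, beside Lmna itself (3.34 ± 0.09). Lrat, which stores retinol as an ester (-1.5 ± 0.34), Clcn1 (-1.25 ± 0.24), Bdh1, an enzyme of ketone use (-1.11 ± 0.18), Acot1, an acyl-CoA thioesterase (-0.9 ± 0.25), Kcnv2 (-0.88 ± 0.19) and Pfkfb1 (-0.88 ± 0.22) were lower. Acot1 was not called without the third control of batch LC (-0.41, edgeR adjusted p = 0.171) or without the first lamin C library or the third lamin C library (-0.83 and -0.89, edgeR adjusted p = 0.0835 and 0.0639). It was also not called with the late-numbered controls left out (-0.41, edgeR adjusted p = 0.193), with the compared groups alone (-0.89, edgeR adjusted p = 0.0792) or by limma-trend on log2(FPKM + 0.1) (-0.77, adjusted p = 0.0515). Pfkfb1 was not called without the first control (-0.57, edgeR adjusted p = 0.103) or the first lamin C library (-0.76, edgeR adjusted p = 0.0675). Matrix genes were higher in 28 of 30 cases (30 adjusted over the list alone), at a median of 1.24 (camera adjusted p = 6.8e-55, and adjusted p = 0.024 with an estimated correlation). Timp1 stood at 3.08 ± 0.26 and Postn at 2.75 ± 0.22. Fibroblast markers were higher in 5 of 10 cases by either adjustment (camera adjusted p = 7.4e-05, and adjusted p = 0.15 with an estimated correlation). Macrophage markers were higher in 14 of 16 cases by either adjustment (camera adjusted p = 2.3e-33, and adjusted p = 0.0043 with an estimated correlation). Cd68 stood at 1.11 ± 0.09 and C1qb at 0.91 ± 0.07. Markers of T and natural killer cells, at low counts, were higher in 5 of 14 cases (10 adjusted over the list alone), at a median of 1.58 (camera adjusted p = 4.1e-07, and adjusted p = 0.024 with an estimated correlation). Interferon genes were higher in 21 of 29 cases (27 adjusted over the list alone) (camera adjusted p = 4.4e-19, and adjusted p = 0.083 with an estimated correlation). Zbp1 stood at 1.54 ± 0.21 and Ifit1 at 1.24 ± 0.15. 12 of 22 stress response targets were higher and 2 lower (13 and 2 adjusted over the list alone), with Psat1 at 0.85 ± 0.14 (camera adjusted p = 4.1e-07, and adjusted p = 0.024 with an estimated correlation). Fetal and stress genes were higher in 7 of 14 cases (9 adjusted over the list alone) (camera adjusted p = 1.8e-09, and adjusted p = 0.083 with an estimated correlation). Nppa stood at 3.07 ± 0.36 and Nmrk2 at 2.91 ± 0.32. Genes of fatty acid oxidation were lower in 16 of 25 cases (21 adjusted over the list alone), at a median of -0.28, with Etfa at -0.42 ± 0.08 (camera adjusted p = 5.3e-11, and adjusted p = 0.13 with an estimated correlation). Respiratory chain genes were lower in 17 of 35 cases (29 adjusted over the list alone), at a median of -0.22, with Sdha at -0.33 ± 0.06 (camera adjusted p = 2.8e-11, and adjusted p = 0.26 with an estimated correlation). Under library totals only 5 respiratory chain genes (median -0.1) and 8 fatty acid oxidation genes (median -0.17) were called lower. In both lists 0 were called higher. Calcium handling genes were lower in 5 of 15 cases (8 adjusted over the list alone) (camera adjusted p = 4.8e-05, and adjusted p = 0.029 with an estimated correlation). Ryr2 stood at -0.42 ± 0.07 and Trdn at -0.31 ± 0.05. Endothelial markers were lower in 2 of 12 cases (4 adjusted over the list alone) (camera adjusted p = 0.003, and adjusted p = 0.25 with an estimated correlation). By camera with its preset correlation the cell cycle, MAPK, p53, heat shock and atrial lists were also higher, and the sarcomere, ion channel, mitochondrially encoded and glycolysis lists lower. With an estimated correlation none of these passed (camera adjusted p between 0.083 and 0.39). Without the third lamin C library the atrial and glycolysis lists did not pass (adjusted p = 0.086 and 0.127), nor did they without the first control (adjusted p = 0.0701 and 0.0638) or the second (adjusted p = 0.0558 and 0.0802). The number of changed genes fell to 1507 without the first and to 1752 without the third lamin C library, and with library totals, which moved the median by 0.11, 90.8% of 3172 called genes were higher, against 58.9%.

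Lamin A was compared with hearts labelled Lmna shRNA in batch LA in the same way, and metabolic, contractile and interferon genes moved toward the control. AI593442 (3.18 ± 0.19), Scn4b (3.06 ± 0.36), Ces1d (2.85 ± 0.31) and Pacsin1, an adaptor of endocytosis (2.44 ± 0.32), had large rises. The short mitochondrial genes mt-Atp8 (3.02 ± 0.93) and mt-Nd4l (2.41 ± 0.44) are uncertain because nuclear copies exist. Without the third lamin A library mt-Atp8 stood at 1.28 and was not called (edgeR adjusted p = 0.296), nor was it without the second library or the third library labelled Lmna shRNA (2.65 and 3.16, edgeR adjusted p = 0.0774 and 0.051) or with limma-trend (adjusted p = 0.0558). Cnn1, a smooth muscle calponin (-3.42 ± 0.27), Sema3e, a guidance molecule (-3.42 ± 0.27), Serpinb1a (-3.25 ± 0.16), Star, a cholesterol transporter of mitochondria (-2.8 ± 0.15), Cd24a (-2.68 ± 0.17) and Serpinb9b (-2.6 ± 0.22) had large falls. Fatty acid oxidation genes rose in 23 of 25 cases (camera adjusted p = 1.2e-29, and adjusted p = 0.032 with an estimated correlation). Acsl1 rose by 0.94 ± 0.09 and Acadm by 0.8 ± 0.06. Respiratory chain genes rose in 34 of 35 cases (35 adjusted over the list alone), with Sdhb at 0.72 ± 0.07 (camera adjusted p = 3.8e-29, and adjusted p = 0.089 with an estimated correlation). 12 of 13 mitochondrially encoded genes rose, with mt-Co1 at 0.76 ± 0.07 (camera adjusted p = 3.9e-11, and adjusted p = 0.047 with an estimated correlation). Ion channel genes rose in 15 of 22 cases (camera adjusted p = 1.1e-10, and adjusted p = 0.047 with an estimated correlation). Kcnj3, a subunit of the acetylcholine-activated potassium channel, rose by 1.13 ± 0.15. Sarcomere genes rose in 11 of 18 cases (12 higher and 1 lower adjusted over the list alone), with Tnni3 at 0.85 ± 0.08 (camera adjusted p = 1.2e-06, and adjusted p = 0.047 with an estimated correlation). Interferon genes fell in 27 of 29 cases (camera adjusted p = 1.3e-27, and adjusted p = 0.047 with an estimated correlation). Irf7 fell by 1.37 ± 0.11 and Ifit3 by 1.29 ± 0.13. Targets of p53 fell in 12 of 19 cases and rose in 2, with Trp53inp1 at -1.12 ± 0.11 (camera adjusted p = 2.2e-06, and adjusted p = 0.032 with an estimated correlation). Matrix genes fell in 18 of 30 cases (22 lower and 2 higher adjusted over the list alone) (camera adjusted p = 1e-06, and adjusted p = 0.45 with an estimated correlation). Tgfb2 fell by 0.88 ± 0.13 and Bgn by 0.65 ± 0.12. Fibroblast markers fell in 3 of 10 cases (camera adjusted p = 0.37). Macrophage markers fell in 7 of 16 cases (8 adjusted over the list alone) (camera adjusted p = 0.012, and adjusted p = 0.47 with an estimated correlation). Lgals3 fell by 1.66 ± 0.14 and C1qa by 0.28 ± 0.06. Unfolded protein response genes rose in 7 of 13 cases and fell in 2 (9 and 2 adjusted over the list alone), against 2 and 2 under library totals (camera adjusted p = 0.096). The chaperone Hspa5 rose by 0.51 ± 0.12 and Hyou1 by 0.5 ± 0.11. Of the stress response targets 4 rose and 4 fell, and Gdf15 rose by a further 1.19 ± 0.16 (camera adjusted p = 0.9). Skeletal muscle markers fell in 5 of 8 cases (camera adjusted p = 0.00039, and adjusted p = 0.032 with an estimated correlation). Endothelial markers rose in 9 of 12 cases (camera adjusted p = 0.00017, and adjusted p = 0.15 with an estimated correlation), and markers of T and natural killer cells fell in 6 of 14 (9 adjusted over the list alone) (camera adjusted p = 0.0035, and adjusted p = 0.15 with an estimated correlation). Under library totals 4 endothelial markers were called higher and 0 lower. Sarcomere genes then held 7 higher and 3 lower calls, and calcium handling genes 4 and 5. The list of fetal and stress genes was also lower by camera with its preset correlation, and that of calcium handling higher. Neither passed with an estimated correlation (camera adjusted p = 0.45 and 0.1). None of 15 cell cycle genes was called, and their median was -0.17 (camera adjusted p = 0.46). Counts not given by both adjustments were equal. The edgeR test called 5330 genes, 2881 higher and 2449 lower. With library totals, which moved the median by -0.2, 17.1% of 7485 called genes were higher, against 54.1%.

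Hearts with shRNA and lamin A differed from the controls of batch LA in 8266 genes by the edgeR test, 4314 higher and 3952 lower, of which 1736 and 447 differed by at least 2-fold. Sprr1a (7.21 ± 0.54), Cthrc1 (6.93 ± 0.63), Thbs4 (6.56 ± 0.37), Timp1 (6.07 ± 0.24) and Fmod (5.92 ± 0.54) were far above the control, while Clcn1 (-2.64 ± 0.27), Efnb3, an ephrin (-2.46 ± 0.13), Kcnv2 (-2.38 ± 0.2), Myh7b (-2.13 ± 0.13), Mylk4 (-2.01 ± 0.22) and Lgi1 (-1.96 ± 0.23) were far below it. All 30 matrix genes were higher by either adjustment, at a median of 2.63 (camera adjusted p = 8.6e-49, and adjusted p = 0.023 with an estimated correlation). Postn stood at 4.46 ± 0.23 and Lox at 4.44 ± 0.24. Fibroblast markers were higher in 8 of 10 cases and lower in 1, with Mfap5 at 2.89 ± 0.15 (camera adjusted p = 1.5e-06, and adjusted p = 0.11 with an estimated correlation). Macrophage markers were higher in 14 of 16 cases and lower in 1 (camera adjusted p = 1.4e-29, and adjusted p = 0.0051 with an estimated correlation). Cd68 stood at 2.24 ± 0.08 and C1qc at 1.65 ± 0.07. Markers of T and natural killer cells were higher in 3 of 14 cases by either adjustment, at a median of 1.03 (camera adjusted p = 0.21). Fetal and stress genes were higher in 13 of 14 cases (14 adjusted over the list alone) (camera adjusted p = 1.8e-08, and adjusted p = 0.11 with an estimated correlation). Nmrk2 stood at 5.19 ± 0.31 and Ankrd1 at 2.41 ± 0.2. Stress response targets were higher in 15 of 22 cases and lower in 2 (17 and 2 adjusted over the list alone) (camera adjusted p = 5.4e-08, and adjusted p = 0.023 with an estimated correlation). Gdf15 stood at 5.41 ± 0.24 and the folate enzyme Mthfd2 at 1.81 ± 0.14. Unfolded protein response genes were higher in 9 of 13 cases and lower in 1 (10 and 2 adjusted over the list alone) (camera adjusted p = 0.012, and adjusted p = 0.42 with an estimated correlation). This list did not pass without the second lamin A library (adjusted p = 0.0562). Pdia4 stood at 0.94 ± 0.12 and Creld2 at 0.87 ± 0.11. All 15 cell cycle genes were higher, with Birc5 at 1.83 ± 0.26 (camera adjusted p = 0.00011, and adjusted p = 0.41 with an estimated correlation). Genes of fatty acid oxidation were lower in 24 of 25 cases, with Ppargc1a, a coactivator of mitochondrial genes, at -1.26 ± 0.11 (camera adjusted p = 2.5e-19, and adjusted p = 0.051 with an estimated correlation). Respiratory chain genes were lower in 35 of 35 cases, with Sdha at -0.77 ± 0.06 (camera adjusted p = 3.8e-17, and adjusted p = 0.2 with an estimated correlation). Ion channel genes were lower in 18 of 22 cases and higher in 2, with Abcc9 at -1.13 ± 0.08 (camera adjusted p = 2e-12, and adjusted p = 0.033 with an estimated correlation). 12 of 15 calcium handling genes were lower, with Pln at -1 ± 0.07 (camera adjusted p = 9.4e-06, and adjusted p = 0.023 with an estimated correlation). Sarcomere genes were lower in 14 of 18 cases by either adjustment (camera adjusted p = 1.4e-06, and adjusted p = 0.042 with an estimated correlation). Under library totals 11 sarcomere genes were called lower and 2 higher, and 8 calcium handling genes lower and 2 higher. By camera with its preset correlation the interferon, heat shock, MAPK and p53 lists were also higher, and the mitochondrially encoded and glycolysis lists lower. Of the 18 lists called in this comparison 6 passed with an estimated correlation, and none of these lists was among them. The glycolysis list did not pass without the first or the second lamin A library (adjusted p = 0.0509 and 0.0558). With library totals, which moved the median by 0.24, 81.3% of 9436 called genes were higher, against 52.2%.

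**Figure D2:**
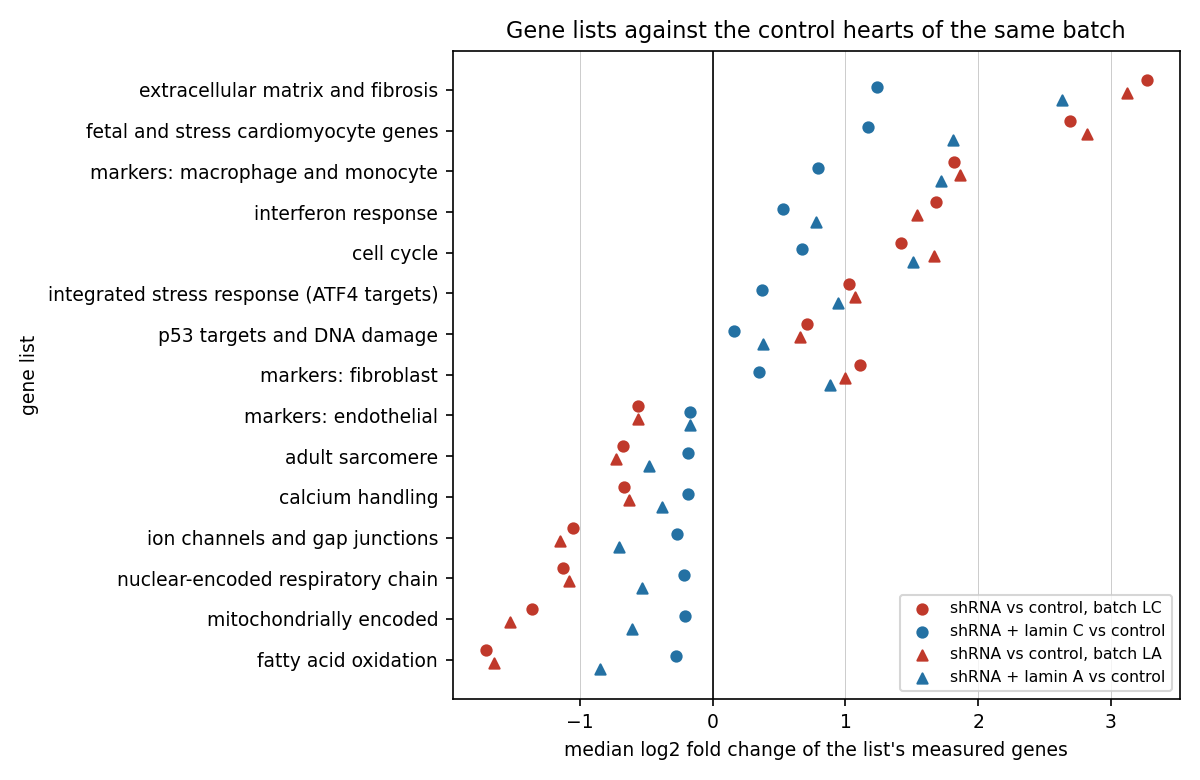
Median log2 fold change of the measured genes of 15 gene lists (rows) against the control hearts of the same batch, for hearts labelled Lmna shRNA (red) and for hearts with shRNA and an added lamin (blue), in batch LC (circles, lamin C) and batch LA (triangles, lamin A). Matrix genes had medians of 3.27 and 1.24 in batch LC and of 3.12 and 2.63 in batch LA; scaling by library totals moved all positions to the right, and the endothelial median with lamin A turned from -0.17 to 0.06.

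How far each lamin moved the shRNA-responsive genes was then measured with a score whose genes were chosen in the other batch. The score is the mean log2 CPM of the genes called between hearts labelled Lmna shRNA and controls in the other batch, each signed by its direction there. In batch LC, over 10975 genes, hearts labelled Lmna shRNA lay 0.9854 above the controls and hearts with lamin C lay 0.2855 above them. In batch LA, over 11247 genes, hearts labelled Lmna shRNA lay 0.9297 and hearts with lamin A 0.5884 above the controls. Hearts with lamin C thus kept 29% ± 6.46 (SD, n = 3; range 21.7 to 34.1) of the shRNA shift of their batch and hearts with lamin A 63.3% ± 3.96 (range 59.4 to 67.4). The libraries of the lamins did not overlap, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow; each difference between groups within a batch gave the same p. Among genes at least 2-fold higher with shRNA in batch LA, 78% of 2816 were lowered by lamin C in batch LC by the edgeR test and 39.7% were called higher than the control. Of 2894 such genes chosen in batch LC, 40.9% were lowered by lamin A in batch LA and 70.4% were called higher than the control. For genes at least 2-fold lower with shRNA, lamin C raised 84.8% of 1376 and lamin A 65.7% of 1479, and 28.5% and 75.1% were called lower than the control.

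**Figure D3:**
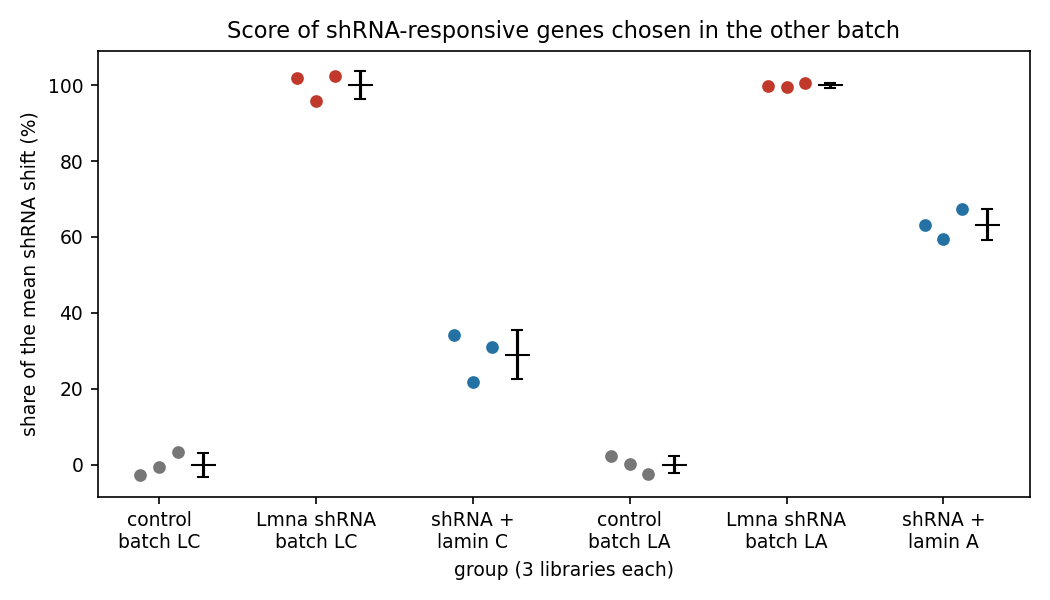
Score of shRNA-responsive genes chosen in the other batch, as a percentage of the mean distance between hearts labelled Lmna shRNA (100) and controls (0) of the same batch, for each of the 18 libraries by group; points are libraries, and the black bar beside them is the mean with its SD. The 3 libraries with lamin C lie between 21.7 and 34.1 and the 3 with lamin A between 59.4 and 67.4.

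The effects of the 2 lamins on hearts labelled Lmna shRNA were compared by testing the difference of the within-batch effects, in which lamin and batch are confounded. Matrix, macrophage and stress genes were lower with lamin C relative to lamin A. All 30 matrix genes differed in that direction (camera adjusted p = 4.5e-37, and adjusted p = 0.051 with an estimated correlation). Timp1 stood at -3.17 ± 0.25, Lox at -2.99 ± 0.28 and Thbs1 at -2.39 ± 0.27. Fibroblast markers were lower in 7 of 10 cases, with Mfap5 at -1.81 ± 0.19 (camera adjusted p = 1.4e-06, and adjusted p = 0.11 with an estimated correlation). Macrophage markers were lower in 12 of 16 cases (13 adjusted over the list alone) (camera adjusted p = 1.5e-15, and adjusted p = 0.035 with an estimated correlation). Cd68 stood at -1.22 ± 0.11 and C1qa at -0.93 ± 0.09. Stress response targets were lower in 11 of 22 cases and higher in 1 (16 and 1 adjusted over the list alone) (camera adjusted p = 1.6e-08, and adjusted p = 0.035 with an estimated correlation). Gdf15 stood at -1.89 ± 0.24, Nupr1 at -1.57 ± 0.21 and Mthfd2 at -1.51 ± 0.19. Unfolded protein response genes were lower in 11 of 13 cases (11 lower and 1 higher adjusted over the list alone) (camera adjusted p = 9.5e-08, and adjusted p = 0.11 with an estimated correlation). Sdf2l1 stood at -1.44 ± 0.25 and Creld2 at -1.18 ± 0.16. Fetal and stress genes were lower in 8 of 14 cases (9 adjusted over the list alone) (camera adjusted p = 5.8e-05, and adjusted p = 0.25 with an estimated correlation). Nmrk2 stood at -2.47 ± 0.35 and Ankrd1 at -1.4 ± 0.27. Fatty acid oxidation genes were higher in 19 of 25 cases (21 higher and 1 lower adjusted over the list alone), with Ppargc1a at 0.98 ± 0.15 (camera adjusted p = 6.2e-15, and adjusted p = 0.11 with an estimated correlation). Respiratory chain genes were higher in 26 of 35 cases (33 adjusted over the list alone), with Sdha at 0.55 ± 0.09 (camera adjusted p = 3.3e-15, and adjusted p = 0.25 with an estimated correlation). Ion channel genes were higher in 15 of 22 cases (18 adjusted over the list alone), with Kcnd3 at 0.89 ± 0.12 (camera adjusted p = 8.6e-10, and adjusted p = 0.08 with an estimated correlation). Interferon genes were lower in 8 of 29 cases (10 adjusted over the list alone), with Ifi27l2a at -1.13 ± 0.21 (camera adjusted p = 0.00013, and adjusted p = 0.49 with an estimated correlation). Targets of p53 were lower in 4 of 19 and higher in 1 (5 and 2 adjusted over the list alone), with Phlda3 at -0.9 ± 0.12 (camera adjusted p = 0.12). The sarcomere, calcium handling, mitochondrially encoded and glycolysis lists were also higher by camera with its preset correlation. Of the 14 lists called in this comparison only 2, macrophage markers and stress response targets, passed with an estimated correlation. The mitochondrially encoded list did not pass when any of 4 single libraries was left out, with the largest adjusted p (0.182) without the third library labelled Lmna shRNA of batch LC. The glycolysis list did not pass without the first library labelled Lmna shRNA of batch LA (adjusted p = 0.0592). Among protein-coding genes at 5 CPM or more, large differences were those of Clcn1 (2.62 ± 0.62), Cngb3 (2.33 ± 0.32), Mylk4 (2.06 ± 0.32), Scn4b (2.02 ± 0.54), Lgi1 (1.89 ± 0.38), Chil1 (-3.46 ± 0.76), Prg4, the joint lubricant lubricin (-3.45 ± 0.32), Serpina3n (-3.01 ± 0.37) and Tnc, a matrix glycoprotein of injured tissue (-3 ± 0.48). Chil1 was not called by limma-trend on log2(FPKM + 1) (-1.16, adjusted p = 0.0505), and Scn4b was not called without the second library labelled Lmna shRNA of batch LA (1.77, edgeR adjusted p = 0.0616). The edgeR test called 3350 genes, 1581 higher and 1769 lower. With library totals, which moved the median by -0.11, 25.2% of 3673 called genes were higher, against 47.2%.

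Distances from each lamin group's own controls differed in 2616 genes by the edgeR test, 1303 higher and 1313 lower with lamin C relative to lamin A. Matrix genes were lower in 27 of 30 cases (29 adjusted over the list alone) (camera adjusted p = 1.8e-33, and adjusted p = 0.074 with an estimated correlation). Lox stood at -2.66 ± 0.34 and Col1a2, a chain of type I collagen, at -1.52 ± 0.21. Fibroblast markers were lower in 7 of 10 cases by either adjustment (camera adjusted p = 1.8e-05, and adjusted p = 0.17 with an estimated correlation). Macrophage markers were lower in 11 of 16 cases (13 adjusted over the list alone), with C1qc at -0.92 ± 0.09 (camera adjusted p = 6.4e-15, and adjusted p = 0.074 with an estimated correlation). Adamts4, a protease of matrix proteoglycans (-3.42 ± 0.73), Tnfrsf11b, the osteoprotegerin decoy receptor (-3.32 ± 0.57), Spon2 (-2.96 ± 0.76) and Aldh1a2, which makes retinoic acid (-2.71 ± 0.34), were far lower. Without the third control of batch LC, Adamts4 (-1.31, edgeR adjusted p = 0.0936) and Spon2 (-1.27, edgeR adjusted p = 0.214) were not called. Inmt (2.05 ± 0.46), the protease inhibitor Timp4 (2.04 ± 0.37), Efnb3 (1.78 ± 0.18), Scn4b (1.63 ± 0.38) and Lgals4 (1.59 ± 0.19) were higher. With the late-numbered controls left out Scn4b was not called (1.17, edgeR adjusted p = 0.0503), nor were Adamts4 (-1.12, edgeR adjusted p = 0.101) and Spon2 (-1.13, edgeR adjusted p = 0.312). Spon2 was also not called by limma-trend on log2(FPKM + 0.1) (-2.19, adjusted p = 0.0673). Unfolded protein response genes were lower in 9 of 13 cases and higher in 1 (11 and 1 adjusted over the list alone), with Pdia6 at -0.79 ± 0.14 (camera adjusted p = 2.3e-06, and adjusted p = 0.17 with an estimated correlation). Genes of fatty acid oxidation were higher in 18 of 25 cases (21 adjusted over the list alone), with Slc27a1 at 0.76 ± 0.11 (camera adjusted p = 1.9e-16, and adjusted p = 0.089 with an estimated correlation). B cell markers went the other way from macrophage markers, with 2 of 10 higher by either adjustment at a median of 1.1 (camera adjusted p = 0.038, and adjusted p = 0.37 with an estimated correlation). They did not pass without the first control of batch LC (adjusted p = 0.0777), the third lamin C library (adjusted p = 0.113) or the first control of batch LA (adjusted p = 0.118). None of 14 markers of T and natural killer cells was called, and their median was 0.51 (camera adjusted p = 0.1). By camera with its preset correlation the sarcomere, ion channel, calcium handling, respiratory chain, mitochondrially encoded and core clock lists were also higher. The lists of fetal and stress genes, stress response targets, heat shock, interferon and cell cycle genes were lower. With an estimated correlation 0 of the 17 lists called in this comparison passed. Without the third control of batch LC the interferon and cell cycle lists did not pass (adjusted p = 0.0738 and 0.12). With the late-numbered controls left out the interferon, cell cycle and core clock lists did not pass (adjusted p = 0.0804, 0.147 and 0.0755). The core clock list also did not pass with DESeq2 (adjusted p = 0.125) or limma-trend on log2(FPKM + 1) (adjusted p = 0.135). Of the genes higher than the control with lamin C, 1379 of 1585 were also higher with lamin A, where independent lists would share 382.5, and 1001 of 1105 lower genes were also lower with lamin A, against 244.3. With the late-numbered control of each batch left out, 1713 genes differed, and with library totals, which moved the median by -0.12, 22.3% of 3053 called genes were higher, against 49.8%.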

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

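The tests of the 3 patterns below were chosen after the results were seen, while regrouping the libraries to see how many genes other groupings call was planned before. Differences between the batches were flagged in 3 tests, by a rule that took any test calling at least 1 gene. The shRNA effect differed between the batches in 1 gene, the lamin C and lamin A effects on hearts labelled Lmna shRNA differed in 3350 genes, and the distances of the lamin hearts from their own controls differed in 2616 genes.

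The first pattern was that cardiomyocyte transcripts fell in hearts labelled Lmna shRNA while Lmna did not. A lower share of cardiomyocytes, with the other cells in unchanged proportions, would raise the markers of all other cells together. Over both batches, however, the median of macrophage markers (1.84, lower quartile 1.53) lay 2.37 above that of endothelial markers (-0.53, upper quartile -0.44). A lower share with unchanged proportions of the other cells thus does not account for it. A lower share beside a rise of macrophages or fibroblasts would dilute endothelial markers too, so this gap cannot exclude it. An exchange of some control and shRNA libraries was not seen, since the lowest library labelled shRNA reached 95.7% of its group's shift and the highest control 3.43%. An exchange of the labels of whole groups in both batches would give the same values and was not tested. Whether Lmna transcripts of other cells hide a loss within cardiomyocytes is open, since the change of Lmna over both batches (0.08 ± 0.06, edgeR adjusted p = 0.211) comes from whole tissue and counts per cell type would be needed.

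The second pattern was that lamin C hearts lay nearer to their controls than lamin A hearts. A stronger shRNA effect in batch LA was not seen: over 9693 genes called in both batches its mean size was 1.12, or 95.2% of the 1.17 of batch LC. Scaling did not make the pattern either, since with library totals the lowest lamin A library kept 56.4% of the shift and the highest lamin C library 33.5%. Different amounts of transcript could contribute, as Lmna CPM was 2.36 times higher in lamin C hearts, and with each lamin in a single batch this stays open. Within the groups the order was mixed: the lamin C library with the lowest Lmna (1064 CPM) kept the least of the shift (21.7%), and the lamin A library with the lowest Lmna (501 CPM) kept the most (67.4%).

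The third pattern was that the third control library of batch LC stood with the controls of batch LA. Arntl, a core clock activator, had 0.75, 1.37 and 26.2 CPM in the controls of batch LC and 21.39, 23.87 and 24.02 in those of batch LA, and Dbp, a clock output gene, had 210.08, 205.09 and 34.58 against 44.81, 34.45 and 48.83. On 177 genes that differed between the shRNA hearts of the batches, clock genes left out, that library lay 81% of the way from its batch to batch LA, which fits handling or collection with batch LA. An exchange of control labels between the batches was not seen, because the lowest control of batch LA lay at 90.7%. Time of day alone is open, since on 188 genes with the clock genes included the position was 85.1% and genes free of rhythm would be needed to decide.

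Each within-batch comparison allows 10 groupings of its libraries, too few for a share under 0.05, and in each only 1 grouping, the real one, called as many genes. Every other grouping mixes libraries of both groups, so a real difference becomes spread within groups. Low counts there cannot exclude chance. The highest other groupings called 1 gene for shRNA against control (real 11247), 0 for lamin C against shRNA (9662) and 43 for lamin C against control (2690) in batch LC, and 0 in each of the 3 comparisons of batch LA (10975, 5330 and 8266). For shRNA against control over both batches 1 of 100 groupings, the real one, called as many as 12899 genes, and the highest other called 8546. The difference of the shRNA effects was reached by 14 of 100 groupings, 7 of which kept the shRNA libraries of each batch together. The highest, with 457 genes, kept them together and put the third control of batch LC with the first and second controls of batch LA. Such groupings hold differences between the batches, so they cannot tell whether the 1 gene is more than arbitrary groupings give. The difference of the lamin effects was reached by 8 of 100 (highest 4278) and that of the distances from control by 10 of 100 (highest 5109). Both shares lay above 0.05, so by the limit set beforehand neither count stands out from regroupings. All of these groupings kept the lamin libraries of each batch together, and 12 of the groupings drawn did. Such groupings still hold the whole difference between the lamin hearts, so they cannot tell whether it exceeds what arbitrary groupings give.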

How the results depend on the processing

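All 6 score differences kept their direction in every setting run for the score, which leaves out the fit of the compared groups alone and the replicate block, with lamin C hearts keeping between 24.7% and 32.5% of the shRNA shift and lamin A hearts between 60.6% and 65%. Counts of called genes stayed within 1.5 times of the values given, except in 3 comparisons. For lamin C against control the count of 2690 was 1507 without the first and 1752 without the third lamin C library. It lay between 1507 and 2680 over all single libraries left out, and was 1835, within 1.5 times, with the compared groups alone. The cause was not tested. For the difference of the shRNA effects the count of 1 was 9 with DESeq2, 247 without the filter on low counts, 0 with the compared groups alone, 24 without the late-numbered controls, and between 0 and 47 with single libraries left out, the 47 without the third control of batch LC; the cause was not tested. For the distances from control the count of 2616 was 1713 without the late-numbered controls and between 1780 and 2521 with single libraries left out. Elsewhere, leaving out single libraries gave 10492 to 10876 genes for shRNA against control in batch LC and 10276 to 10403 in batch LA, 8551 to 9198 for lamin C against shRNA, 4097 to 4690 for lamin A against shRNA, 7147 to 7625 for lamin A against control, 12605 to 12896 over both batches and 2478 to 3397 for the difference of the lamin effects. Library totals changed the share of called genes that were higher, as given beside each comparison, and turned the majority for lamin A against shRNA (54.1% higher to 17.1%). Limma-trend on log2(FPKM + 1) turned it for shRNA against control (46.1% higher in batch LC, 46.2% in batch LA and over both), lamin C against shRNA (53.1%), lamin A against control (47%) and the difference of the lamin effects (51.3%), and the compared groups alone turned it for lamin C against shRNA (50.4%); the cause was not tested. For the distances from control, 49.8% higher, it lay between 48.4% and 55.5% in settings other than library totals and single libraries left out. Of 162 list calls by camera with its preset correlation, taken over all 10 comparisons, 23 were lost with library totals and 23 with limma-trend on log2(FPKM + 1). A further setting, the compared groups alone, lost 5, while 4 were lost without the late-numbered controls, 3 without the filter on low counts and 2 with DESeq2. With an estimated correlation between 0 and 8 of the 32 lists passed per comparison, against between 3 and 20 with the preset. With single libraries left out, each call was counted once for each library left out in turn. Counted so, list calls were lost 35 times and kept 1261 times. Calls of named genes were lost 19 times, while values of named genes stayed the same 1906 times. Library totals turned the median of glycolysis genes from -0.19 to 0.24 for shRNA against control in batch LC, and from -0.15 to 0.28 over both batches. For lamin C it turned from 0.17 to -0.14 against shRNA and from -0.11 to 0.01 against control, each time without a call. In the same comparisons this scaling moved the median of all genes by 0.43, 0.43, -0.31 and 0.11, so the turn was not particular to glycolysis. Of 276 values of named genes none that was called turned its direction in any setting, and at most 6 lost their call in a setting other than single libraries left out. At this depth 3 counts equal at most 0.108 CPM. In simulated data, with dispersions from the fitted trend and few genes changed, changes of 1.5-fold were found in 71.64% of cases, which need not hold for the real hearts.

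The libraries of a batch share replicate numbers, but the numbers do not pair samples: in 18 pairs of libraries of the same number no correlation of residuals exceeded 0.1 (-0.0459 to 0.0617), and 4 of 18 libraries lay closest to their own number. With the replicate block the counts were 11065, 9391 and 2464 in batch LC (shRNA against control, lamin C against shRNA, lamin C against control), 10775, 5103 and 8051 in batch LA, 12725 over both batches, and 0, 3136 and 2401 for the 3 differences.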

Other observations

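The test in this part, and its genes Cebpb, Il33 and Tnnt1, which lie outside the naming rule, were chosen after the values were seen. Some genes in hearts with an added lamin lay beyond both the controls and the hearts labelled Lmna shRNA. In lamin A hearts these were 194 genes above and 136 below both, without Lmna. Pacsin1, an adaptor of endocytosis, was 2.44 above shRNA and 2.11 above control, Gdf15 1.19 and 5.41, Cebpb 1.18 and 1.28, the cytokine Il33 1.09 and 3.55, and Aldh1a2, which makes retinoic acid, 0.87 and 3.95. In lamin C hearts they were 38 above and 30 below, among them Car3, a carbonic anhydrase (2.03 and 2.27), Tnnt1, the slow skeletal troponin T (1.89 and 1.12), and, as in lamin A hearts, Pacsin1 (1.41 and 2.32).

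Of the 330 genes of lamin A hearts, 12 or 3.64% lay beyond both the same way among the 68 genes of lamin C hearts, where 0.641 would be expected of independent lists, and 0 lay the opposite way. Against shRNA, 81 of the 330 moved the same way in lamin C hearts. That comparison called 4592 of all 17876 genes higher and 5070 lower, so the 81 show no sharing beyond that of all genes. Whether a raised Lmna transcript irrespective of the lamin moved the 330 genes is open. With 68 genes in lamin C hearts the share of 3.64% had no room to pass 20.6%. In 10 simulated draws in which no mean lay beyond both, at most 49 genes were called so in lamin A hearts and 35 in lamin C hearts.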
